A study of Mus musculus with 2 samples.

How the data were processed

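H3K9me3, the trimethylation of lysine 9 of histone H3 that marks repressed chromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse midbrain at embryonic day 12.5. Per the labels, replicate 1 was made from the pooled midbrains of 120 embryos of the B6NCrl strain and replicate 2 from those of 88 embryos, both of mixed sex, with fragments of 300 to 500 bp. The labels number them as separate biological replicates. There was 1 group, so no comparison between conditions was made, and the comparisons are those of the 2 replicates with each other and of peak positions with gene annotation.

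The authors deposited 4 peak lists in narrowPeak format on the mm10 build: a list per replicate, a list called on both replicates pooled, and a list of replicated peaks. Per the deposited notes, the replicated list was derived from the pooled list and both single-replicate lists, and the control alignments entered the peak calls. The aligner, the peak caller, its settings and all versions are not given in the sources used here. Each deposited peak carried a display score, a summit offset in bases, a signal column (narrowPeak column 7), and −log10 p and −log10 q against the control. The signal column is called the enrichment value below. It is the authors' own value, its exact definition was not stated, and it served here to rank, filter and describe peaks. The score column was not used further. Reads per library are unknown from these files, so no counting interval could be given for single peaks, and a region without a peak cannot be told from a region with too few reads. Regions that reads cannot be placed in uniquely may lack peaks for that reason alone.

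Positions were compared with the GRCm38.p6 sequence, the same build as mm10, and the GENCODE vM21 annotation. Genes were 21910 protein-coding and 10142 long noncoding genes on chromosomes 1 to 19, X and Y. A gene body counted as overlapped when at least 1 bp lay under a peak, and a promoter was the gene start with 2 kb on either side. For each of 21 gene lists, the number of members under a replicated peak was set against 10000 random lists, in which each member was replaced by 1 of the 200 genes nearest in length, of the same biotype and outside the list. The two-sided permutation p-values were adjusted by the Benjamini-Hochberg method over the 21 lists. They describe these 2 libraries, since genes are not replicates, and genes of a cluster that lie side by side are not independent. For that reason the lists were also tested with 1000 circular shifts of all peaks along each chromosome, by at least 1 Mb, which keep the spacing of the peaks. The same shifts served for the overlap of the replicates (one-sided), the annotation classes of peak midpoints (two-sided, Benjamini-Hochberg over 5 classes) and the exons of zinc finger genes (one-sided). Classes were assigned in the order promoter, coding exon, other exon, intron and intergenic. The first and final exon were those of the basic transcript with the longest coding sequence. GC content, CpG and soft-masked bases were set against 20 shifts, as values and ranges only. Peaks less than 10 kb apart were merged into domains. Peak density was taken per Mb of assembled sequence.

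The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per list, up to 4 members with the highest enrichment value of a replicated peak over the gene body. For imprinted and germline genes it also took up to 6 by the promoter. It further took the 10 protein-coding genes with the most bases under replicated peaks, the 10 replicated peaks of highest enrichment value, the 5 widest domains with the genes inside, and every promoter member of the midbrain, housekeeping and H3K9me3 machinery lists where there were 5 or fewer. Of the listed symbols, 2 were not found in the annotation. Alternatives were a minimum −log10 q of 2, the pooled list, 500 bp of overlap or of promoter flank, the circular shifts, other merge distances, the peak summit, and each replicate's own strongest peaks, as many as the replicated list holds, in place of the replicated list. Many peaks shared a p-value, with 9000 peaks of replicate 1 and 886 of replicate 2 tied at the last one kept, and ties were put in random order, a choice made after the data were seen. The replicated peaks under a peak of both replicates, and each replicate's whole list, were added as alternatives after the data were seen.

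The code was tested on simulated data. Among 200 random lists of 60 genes with hits set by length alone, 3% had p below 0.05, and with hits raised 2-fold 75% did. These lists held scattered genes with independent hits, so the 3% does not carry over to lists of clustered genes. For olfactory receptor gene bodies, the SD of the count was 7.297 in matched lists and 24.37 under circular shifts. With 30% of 29861 simulated peaks planted in a second set, the overlap was 30.4%, or 29.6 percentage points above the shifts. With 100 of 400 final exons planted under peaks, 105 were found under one. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.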

Results

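The data were 2 H3K9me3 ChIP-seq libraries of mouse midbrain at embryonic day 12.5, from pools of 120 and 88 embryos. Replicate 1 had 65574 peaks covering 20.57 Mb and replicate 2 had 62857 peaks covering 19.52 Mb. The pooled list held 75231 peaks over 28.17 Mb, and the replicated list held 30189 peaks over 16.68 Mb, or 0.62% of the assembled chromosomes. Peaks as called were narrow, with a median width of 249 bp in replicate 1, 244 bp in replicate 2 and 439 bp in the replicated list. The narrowest had 190, 180 and 185 bp, in that order. Lower quartiles were 202 bp in replicate 1 and 197 bp in replicate 2, close to these minima. The peak caller and its settings are unknown, so these widths need not be those of the marked regions. The widest replicated peak spanned 11533 bp. Read depth is unknown, and all coordinates are of mm10. Enrichment values are the authors' own, per peak, and are given without an error because each belongs to a single list.

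The first question was how well the replicates matched. Of the replicate 1 peaks, 37.6% overlapped a replicate 2 peak by at least 1 bp, and 39.2% of the replicate 2 peaks overlapped a replicate 1 peak. Circular shifts of the peaks gave a mean of 1.68% and 1.76%, with highest values of 2.55% and 2.72% (one-sided permutation p = 0.001 for both, the smallest that 1000 shifts can give). Overlap was highest among the strongest peaks. In the 10% of peaks with the lowest p-values, 77.2% of replicate 1 and 78.2% of replicate 2 peaks were found in the other replicate, against 21.9% and 23.8% in the weakest 10%. With a reciprocal overlap of 50% required, the shares were 19.04% and 19.9%. Across 22143 replicated peaks that lay under a peak of both replicates, enrichment values correlated weakly (Spearman's rho = 0.249 across peaks, which are not independent replicates).

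**Figure D1:**
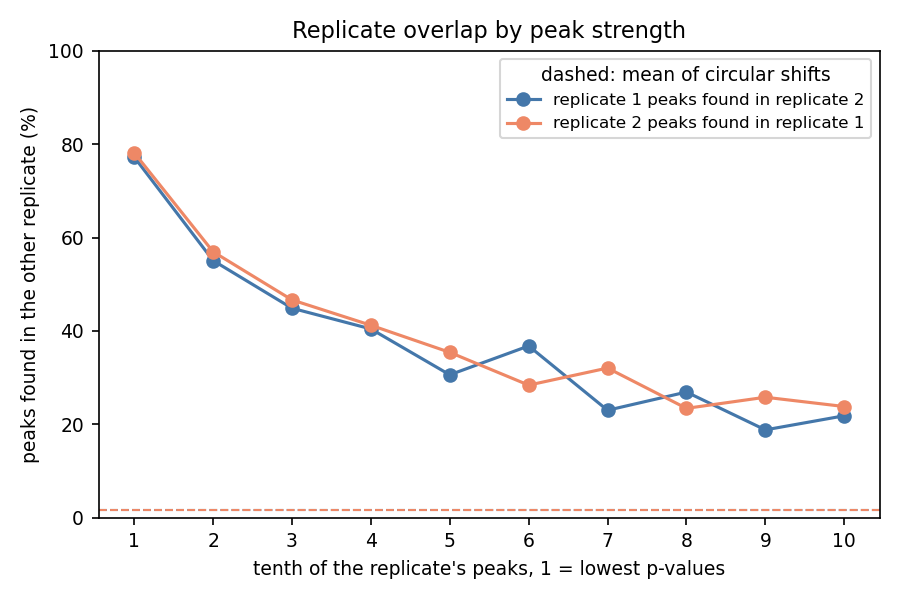
Share of each replicate's peaks (%) that overlapped a peak of the other replicate, by bin of 10% of the peaks ranked by p-value (1 = lowest p-values). Points are single values per bin, and dashed lines are the means of the circular shifts. The share lay at 77.2% and 78.2% in the strongest bin and at 21.9% and 23.8% in the weakest, against 1.68% and 1.76% for the shifts.

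The replicated list kept 40.1% of the pooled peaks. Replicated peaks had a median enrichment value of 3.12 and a median width of 439 bp, and the 45042 pooled peaks left out had medians of 2.53 and 228 bp. Of the replicated peaks, 22143 (73.3%) overlapped a peak in both replicates' own lists, 3191 in replicate 1 only, 4576 in replicate 2 only, and 279 in neither. A listing as replicated was therefore not the same as a call in both libraries.

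Zinc finger genes, which encode a large family of DNA-binding proteins, were among the genes most often under H3K9me3 peaks. The list took protein-coding genes by symbol (Zfp, Zscan and Zkscan), so zinc finger genes with other names count among the other genes below. Of 418 zinc finger genes, 171 (40.9%) had a replicated peak over the gene body, 3.22 times the number in length-matched lists (two-sided permutation p = 0.0002, adjusted p = 0.0006, the smallest that 10000 lists can give). The strongest were Zfp68 (chromosome 5, 138603652 to 138619761), with 11 replicated peaks and a highest enrichment value of 8.34, Zfp810 on chromosome 9 with 7.70, Zfp146 on chromosome 7 with 7.455 and Zfp354c on chromosome 11 with 6.82. In the replicates' own lists the highest values over Zfp68 were 8.53 and 8.18. More of these genes had a peak over the final exon, which often encodes the zinc finger array, than over the first. Of 414 zinc finger genes with 2 or more exons, 121 (29.2%) had the final exon under a peak and 8 (1.93%) the first exon, while the shifts gave means of 16.4 and 5.44 (one-sided permutation p = 0.001 for the difference, the smallest that 1000 shifts can give). Final exons were also longer, with a median of 2249 bp against 131 bp, a difference that the shifts carry too. The final and first exon counts were 111 and 7 without replicate 1, and 109 and 5 without replicate 2. Among zinc finger genes with a peak, 71.2% had it over the final exon, against 9.67% of the other multi-exon coding genes with a peak. At promoters, 32 of 418 zinc finger genes had a peak, 2.53 times the matched lists (adjusted permutation p = 0.00052), but the call was lost with circular shifts (adjusted p = 0.58) and with a promoter of 500 bp on either side (adjusted p = 0.92, with 0.00052 to 0.92 over the alternatives).

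**Figure D2:**
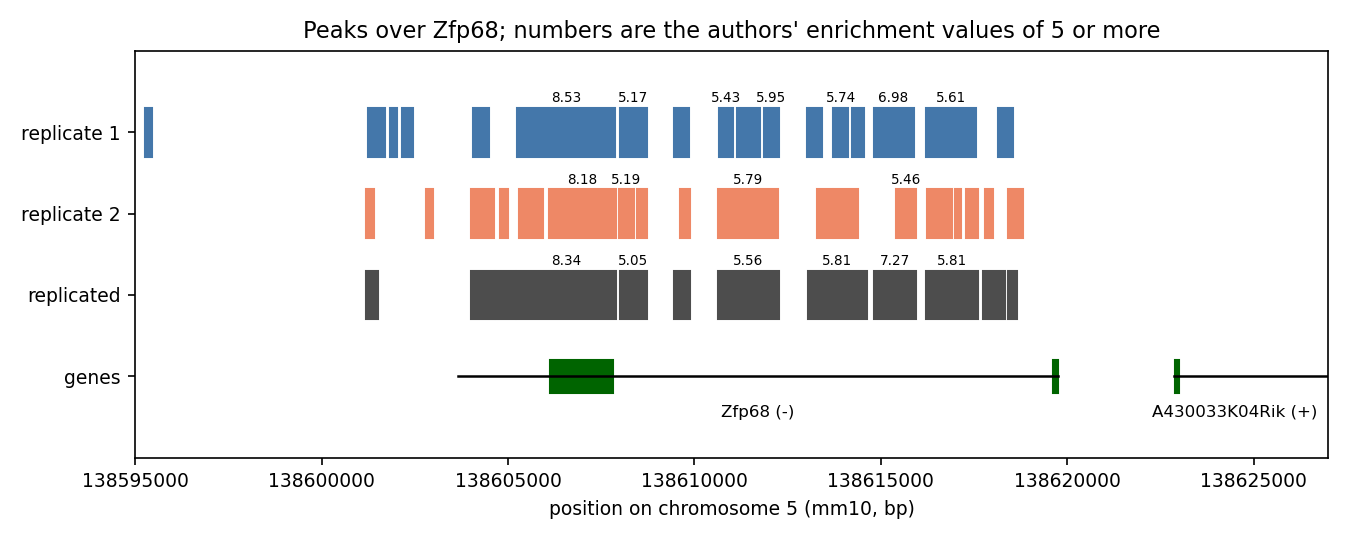
Map of 32 kb of chromosome 5 (position in bp, mm10) with the peaks of replicate 1, replicate 2 and the replicated list over Zfp68 and the start of A430033K04Rik. Boxes on the gene line are the first and final exon, numbers are enrichment values of 5 or more, and the peak of 8.34 covers the final exon of Zfp68 (138606120 to 138607821) while the first exon (138619609 to 138619740) lies under none.

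Clustered protocadherins, cell-surface adhesion molecules of which each neuron expresses its own combination, had the highest share of all lists. Of 56 genes, 52 had a gene body peak (3.12 times the matched lists, adjusted permutation p = 0.0006) and 51 a promoter peak, where 1.54 were expected (33.1 times, adjusted p = 0.00052). The gamma cluster on chromosome 18 held the members with the highest values: Pcdhga1, Pcdhga10, Pcdhga2 and Pcdhga3 share a peak of 7.33 at 37746724 to 37750154, because their gene bodies overlap. The 10 coding genes with the most bases under replicated peaks all lay in this region. Gm42416, Gm37013 and Gm37388, gene models that span the clusters, had 274336, 265858 and 263403 bp, and Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1, Pcdhga4, Pcdhgb2 and Pcdhga5 followed with 89574 to 66132 bp. These counts overlap, since the same peaks lie in several gene bodies. Both protocadherin calls held under every alternative run, with the highest adjusted permutation p, 0.0084 for the gene body and 0.014 for the promoter, under circular shifts.

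Chemosensory receptor genes, which are expressed in the nose, were also over-represented. Of 328 vomeronasal receptor genes, 108 had a gene body peak (3.61 times the matched lists, adjusted permutation p = 0.0006) and 59 a promoter peak (4.72 times, adjusted p = 0.00052), and both calls held under every alternative run, with the highest adjusted p, 0.0084 and 0.017, under circular shifts. Vmn2r10 on chromosome 5 had the highest enrichment value, 6.06, followed by Vmn2r16 and Vmn2r60 at 5.05 and Vmn1r90 at 4.80. Of 1134 olfactory receptor genes, 112 had a gene body peak (1.95 times, adjusted permutation p = 0.0006) and 93 a promoter peak (2.10 times, adjusted p = 0.00052). With circular shifts, which keep peaks and genes in their clusters, both olfactory calls were lost (adjusted permutation p = 0.32 and 0.33, with lowest values over the alternatives of 0.0006 and 0.00052). Olfr943 at 4.67, Olfr870 at 4.33, and Olfr139 and Olfr853 at 4.30 had the highest enrichment values.

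Cyp2 and Cyp3 genes, which encode cytochrome P450 enzymes, and the Speer and Skint families followed. In the Cyp2 and Cyp3 list, 22 of 55 genes had a gene body peak (2.93 times, adjusted permutation p = 0.0006) and 13 a promoter peak (7.74 times, adjusted p = 0.00052), and with circular shifts both calls were lost (adjusted p = 0.14 and 0.07, with lowest values over the alternatives of 0.0006 and 0.00052). Cyp3a11 and Cyp3a44 on chromosome 5 had enrichment values of 4.42, Cyp2c29 on chromosome 19 had 4.30 and Cyp3a16 had 4.17. Of 21 Speer and Skint genes, 9 had a gene body peak (2.13 times, adjusted permutation p = 0.019) and 7 a promoter peak (14 times, adjusted p = 0.00052). The promoter ratio was 7.25 without replicate 1 and 7.104 without replicate 2. The gene body call was lost with circular shifts (adjusted permutation p = 0.26, with 0.0031 to 0.26 over the alternatives), and the promoter call was lost at 500 bp on either side (adjusted p = 0.92, with 0.00052 to 0.92). The leading members were Skint5 at 5.31, Skint9 at 4.67, Skint6 at 4.55 and Skint10 at 4.42, all on chromosome 4.

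Imprinted genes, of which the maternal or the paternal copy is silent, stood out at both positions. Of 53 genes, 42 (79.2%) had a gene body peak (3.59 times the matched lists, adjusted permutation p = 0.0006) and 24 (45.3%) a promoter peak (14.0 times, adjusted p = 0.00052). Over gene bodies the highest enrichment values were at Impact (6.02), Mest (5.81), Grb10 (4.80) and Plagl1 (4.67). At promoters they were at Meg3 (5.18), Peg3 and Usp29 (4.55, a peak shared by their neighbouring starts), Nespas (4.12), Nap1l5 (4.12) and Airn (4.04). Both calls held under every alternative run, with the highest adjusted permutation p, 0.0084 and 0.014, under circular shifts.

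Germline and meiotic genes, which act in germ cells, had 23 of 62 members with a gene body peak (2.11 times, adjusted permutation p = 0.0006) and 17 with a promoter peak (10.3 times, adjusted p = 0.00052). The promoter peaks included Dazl, an RNA-binding protein of germ cells (4.93), Mael (4.75), Meioc (4.55), D1Pas1 (4.46), Nlrp5 (4.04) and Taf7l on the X chromosome (3.92). Over gene bodies Nlrp5, with 38 replicated peaks, reached 5.05. At the Dazl promoter the replicates' own lists had highest values of 7.24 and 3.65. The gene body call was lost without replicate 1, where the ratio was 1.45 (adjusted permutation p = 0.25, with 0.0006 to 0.25 over the alternatives), and the promoter call was not.

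**Figure D3:**
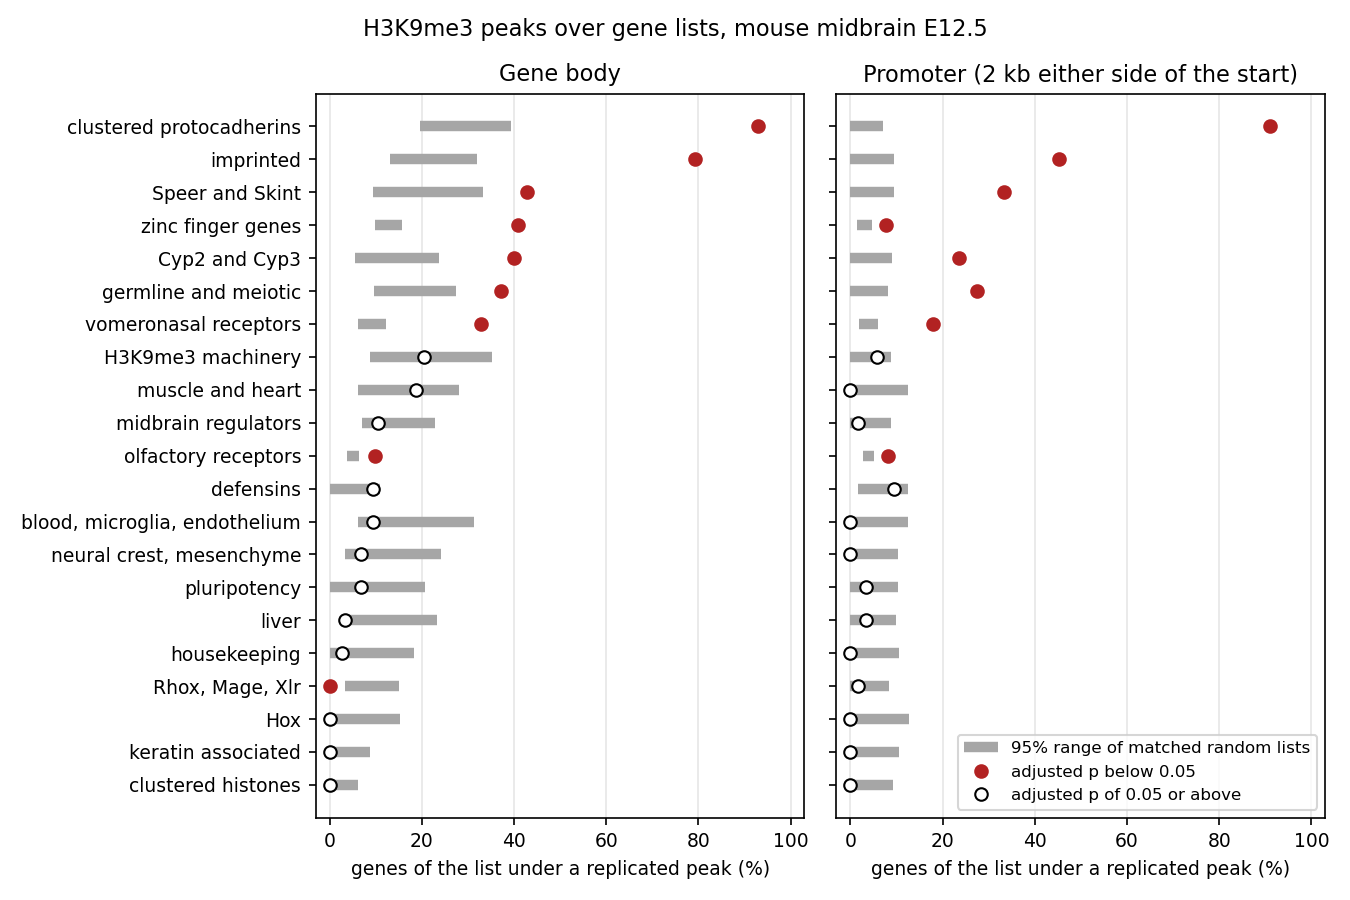
Share of the genes of each list (%) with a replicated peak over the gene body (left) or within 2 kb of the gene start (right). Points are the 21 lists, filled where the adjusted p was below 0.05, and grey bars are the 95% range of 10000 length-matched random lists. Clustered protocadherins lie at 92.9% and 91.1%, imprinted genes at 79.2% and 45.3%, and the midbrain regulators at 10.5% and 1.75%, inside the grey range for both.

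The lists of midbrain regulators, housekeeping genes and the H3K9me3 machinery did not pass the test in either direction with the replicated list. At promoters 2.08, 1.40 and 0.897 members were expected, in that order. The grey range of the matched lists included 0 for each, so the test could not have shown fewer promoter peaks, whatever the count. The same held for housekeeping gene bodies with the replicated list. With the pooled list, 1 of 38 housekeeping genes had a gene body peak, where 6.027 were expected (matched-list range 2 to 11). That ratio, 0.1659, lay at the threshold without a call (adjusted permutation p = 0.05 as rounded). These results therefore leave open whether such peaks are depleted. Of 57 midbrain regulators, 6 had a gene body peak, where 8.24 were expected (adjusted permutation p = 0.56). Sox3 on the X chromosome was the sole member with a replicated peak at the promoter (enrichment value 2.65). With the whole list of replicate 1, 7 members had a promoter peak (ratio 1.732), and with that of replicate 2, 1 did (ratio 0.2816). Neither was called. The gene body count was 1 at 500 bp of overlap (ratio 0.1908, adjusted permutation p = 0.092) and 3 with peaks under both replicates (0.4484). Over the alternatives the gene body ratio of this list ran from 0.1908 to 0.8284, with no call. Ddc, an enzyme of dopamine synthesis that is also in the imprinted list, had 3.79, Pax7 had 3.29 and Pax5 had 3.16 over the gene body. Of 38 housekeeping genes, 1 had a gene body peak (Tbp, 3.03) and 0 had a promoter peak, where 3.26 and 1.40 were expected (adjusted permutation p = 0.44 and 0.69). The genes of the H3K9me3 machinery itself had 7 of 34 members with a gene body peak, led by Atf7ip (3.73), Fam208a (3.54), Setdb1 (3.49) and Zfp809 (3.16). Over the Fam208a gene body, the own list of replicate 2 had 0 peaks. Morc2a and Fam208a had a promoter peak (adjusted permutation p = 1 for gene bodies and 0.69 for promoters). With the whole list of replicate 1 the promoter ratio of the machinery list was 3.136, past the threshold (adjusted permutation p = 0.046, with 0.046 to 1 over the alternatives). Without replicate 1 this list had 4 members with a gene body peak (ratio 0.5291, against 0.9387 with the replicated list) and 0 with a promoter peak, and without replicate 2 it had 9 and 3. Without replicate 1 no midbrain regulator had a promoter peak and no housekeeping gene a gene body peak, and without replicate 2 the latter count was 2.

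Lists of other tissues and cell types did not pass the test for gene bodies in either direction. Of 30 liver genes 1 had a gene body peak (Cyp3a11), of 32 muscle and heart genes 6 (Ttn at 3.54 the highest), of 32 blood, microglia and endothelium genes 3 (Tek, Cx3cr1 and Flt1), of 29 neural crest and mesenchyme genes 2 (Ets1 and Pdgfrb), and of 29 pluripotency genes 2 (Trim71 at 4.66 and Zfp42 at 3.66), with adjusted permutation p from 0.41 to 0.93. Defensins had 6 of 64 genes under a peak (adjusted permutation p = 0.34), led by Defb33 at 3.92. None of 39 Hox, 65 clustered histone and 57 keratin-associated genes had a gene body peak, and at these sizes the test was not passed (adjusted permutation p = 0.29, 0.52 and 0.50). For these lists and for pluripotency the grey range of the matched lists included 0, so the test could not have shown fewer peaks. The list of Rhox, Mage and Xlr genes, many of them on the X chromosome, had 0 of 60 genes under a peak where 4.87 were expected (adjusted permutation p = 0.012), but not with circular shifts, which keep the low density of X, where 1.37 were expected (adjusted p = 0.85, with 0.014 to 0.85 over the alternatives). The call was also lost without replicate 2, where the ratio was 0.1872. Without replicate 2 the gene body counts were 2 for liver and 6 for blood, microglia and endothelium, and without replicate 1 the count for Hox was 1, with no call in these lists.

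Most replicated peaks were intergenic. Of the 29933 peaks on chromosomes, 61.1% had the midpoint between genes, 1.204 times the shifts (adjusted p = 0.0033, two-sided permutation test), and 30.2% in introns, 0.741 times (adjusted p = 0.0033). Coding exons held 522 midpoints (1.74%), 1.35 times the shifts (adjusted permutation p = 0.0033). Promoters held 4.60%, where the shifts gave 4.79% (adjusted permutation p = 0.76), a difference that did not pass the test. In sequence, peaks had 45.3% GC, above the range of 20 shifts (41.5% to 42.7%). The soft-masked share was 33.6% (shifts 32.7% to 35.1%) and CpG was 0.870 per 100 bases (0.809 to 0.903), both within the range. The shifts could move peaks into regions where reads cannot be placed uniquely. The soft-masked share therefore cannot show whether the mark favours or avoids such sequence.

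Chromosome 7 was the densest, with 34.6 replicated peaks per Mb, followed by chromosome 17 with 22.3, against a median of 10.3 and a mean of 12.6 ± 6.86 (SD) over the 19 autosomes. The X chromosome had the lowest density apart from Y, 2.40 per Mb, below chromosome 1 with 5.70. Against all chromosomes but Y this was a ratio of 0.205, and without replicate 2 the ratio was 0.3994. The replicates were alike on every autosome, with ratios of replicate 1 to replicate 2 peaks from 0.990 to 1.075, and differed on X, where replicate 1 had 2300 peaks and replicate 2 had 1176, a ratio of 1.956 (exact 95% interval 1.82 to 2.10, for counting error). With −log10 q of at least 2 there were 250 and 266 peaks on X, a ratio of 0.9398 (0.788 to 1.121), against 0.6495 to 0.773 on autosomes. The Y chromosome had 20 and 19 peaks.

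**Figure D4:**
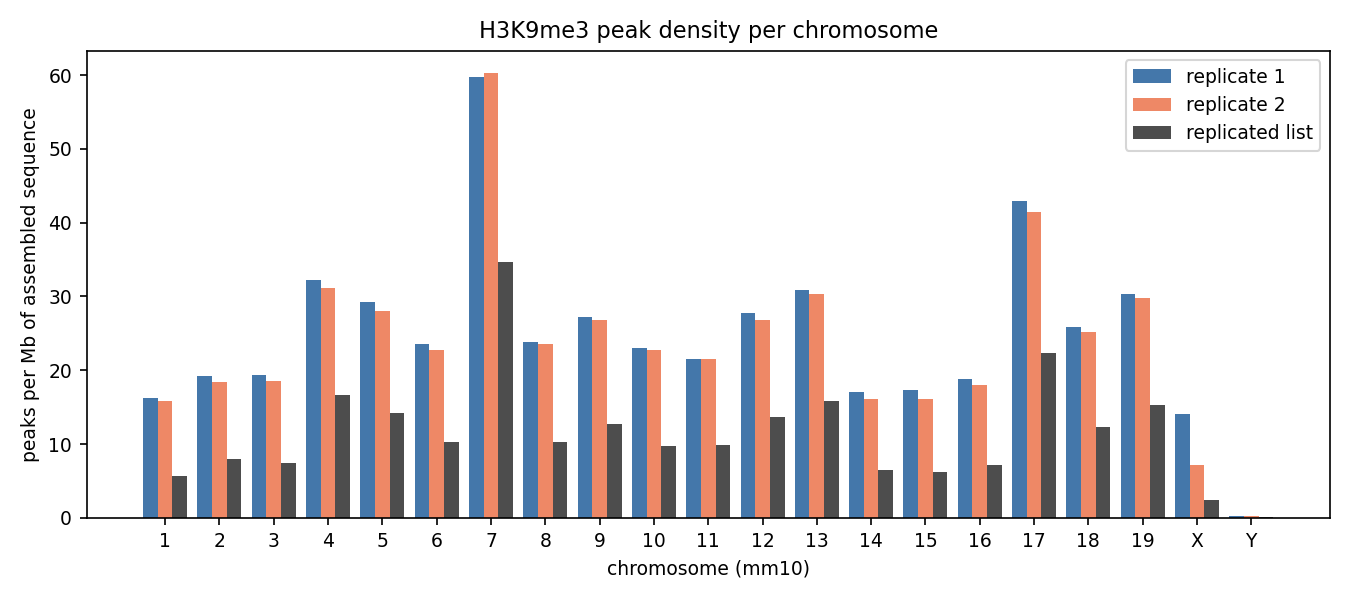
Peaks per Mb of assembled sequence on each mm10 chromosome in replicate 1, replicate 2 and the replicated list. Bars start at 0. Chromosome 7 has 59.7, 60.3 and 34.6 peaks per Mb, and X has 14.1, 7.19 and 2.40.

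After peaks less than 10 kb apart were merged into domains, 755 domains had 5 or more peaks and held 44.6% of the replicated peaks on chromosomes, and 9884 peaks stood alone. These sizes follow the merge distance: the widest domain was 159.7 kb at 5 kb and 2988 kb at 50 kb, where 11623 and 5217 peaks stood alone. At 10 kb the widest, 303.4 kb on chromosome 7 (10177760 to 10481207), had 124 peaks and held the vomeronasal receptor genes Vmn1r66 and Vmn1r67. With the replicated peaks under a peak of both replicates the widest was 301.9 kb. A domain of 301.9 kb at 17885726 to 18187666 of the same chromosome had 187 peaks, with Gm5155, Ceacam11, Ceacam13, Ceacam12 and Igfl3, and the adjoining one of 278.2 kb (17595181 to 17873332) held Ceacam5, Ceacam14 and Gm5155. The others were 279.6 kb on chromosome 5 over Vmn2r15, Vmn2r16 and Vmn2r17, and 263.6 kb on chromosome 7 over Scgb2b26, Scgb2b27 and Scgb1b27.

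The replicated peak of highest enrichment value, 9.77, lay in Klf14 on chromosome 6, at 30957021 to 30959169. Klf14 is a zinc finger transcription factor gene outside the zinc finger list. The midpoint of this peak was within 2 kb of the gene start. A peak on an unlocalised scaffold of chromosome 4 had 9.35. Zfp68 held a peak of 8.34 with its midpoint in coding exon (138605238 to 138607901) and an intronic peak of 7.27 (138614803 to 138615936). The peak of 7.70 in Zfp810 had its midpoint in coding exon and that of 7.455 in Zfp146 in an intron. The rest of the 10 lay in an intron of the noncoding gene Gm26573 on chromosome 4 (7.89), in the protocadherin gamma cluster (7.33), 6597 bp from the nearest gene, Vmn1r238, on chromosome 18 (7.24), and over Ccdc177 and Gm26796 on chromosome 12 (7.20).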

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

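The comparison of ranks was chosen after the data were seen. The replicated list held 256 peaks on unplaced or unlocalised scaffolds, sequence that none of the gene or chromosome comparisons used. They were 0.848% of the list, on 24 scaffolds, and 62 of them lay on a single unplaced scaffold, where replicate 1 and replicate 2 each had 67 peaks. Of the 100 replicated peaks with the lowest p-values, 38 were on scaffolds, against 7 of the 100 with the highest enrichment values. The median enrichment value was 3.71 in the first set and 6.26 in the second. No explanation was tested for these peaks.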

How the results depend on the processing

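The restriction to peaks under a peak of both replicates and the use of each replicate's whole list were chosen after the data were seen, as were the measures of spread. These were the 95% Fisher interval for rho, the 95% Wilson interval for the replicated share, and for densities, domains and sequence the SD of the values without either replicate, of which there are 2. Of 467 values under an alternative, 426 kept their side of the threshold or moved by less than the spread (counts, by no more than 1.5 times), 17 lost their call, 5 gained one, 19 moved by more than the spread (counts, by more than 1.5 times) and 0 called results reversed. Among the 426 were 37 ratios, of 12 results with no call in either setting, that crossed 1, such as 2.033 with circular shifts for Rhox, Mage and Xlr promoters (0.479 with matched lists). The causes were not tested. With circular shifts, which keep the clusters of peaks and genes together, the number of lists above expectation was 5 for gene bodies and 5 for promoters, against 8 and 8 with matched lists. The gene body ratios whose call was lost there were 1.557 for olfactory receptors, 2.175 for Cyp2 and Cyp3, 2.009 for Speer and Skint and 0 for Rhox, Mage and Xlr, and the promoter ratios were 1.468 for zinc finger genes, 1.749 for olfactory receptors and 4.452 for Cyp2 and Cyp3. With 500 bp around the gene start, the promoter ratio of zinc finger genes was 1.357 and that of Speer and Skint 3.72, both without a call. The gene body call of Speer and Skint was also lost with the pooled list (1.635) and with the whole lists of replicate 1 (1.508) and replicate 2 (1.569). That of Rhox, Mage and Xlr was lost with those lists (0.4626 and 0.3831) and at 500 bp of overlap (0), and was 0 to 0.1872 without either replicate, with no call without replicate 2. That of the germline genes had ratios of 1.449 to 2.032 without either replicate, the lower one, without replicate 1, with no call. The calls gained were at promoters: higher than matched lists for defensins with the pooled list (2.552) and the whole list of replicate 2 (2.359) and for the H3K9me3 machinery with the whole list of replicate 1 (3.136), and lower for clustered histones with both whole lists (0 and 0).

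With −log10 q of at least 2, rho between replicates was 0.2168, the replicated share of pooled peaks was 59.45% and GC was 45.29%. With −log10 p in place of the enrichment value, rho was 0.3106. With either replicate left out, the density of chromosome 7 against all chromosomes but Y was 2.669 to 2.836 (2.96 with the replicated list) and that of X was 0.232 to 0.3994 (0.205). The share of peaks in domains was 37.91% to 40.8%, GC was 45.52% to 45.56%, the soft-masked share was 33.76% to 34.37% and CpG per 100 bases was 0.8844 to 0.9432, which without replicate 2 lay above its shifts. The share of peaks in domains was 35.59% with a merge distance of 5 kb and 59.1% with 50 kb. Replicated peaks under a peak of both replicates had 45.33% GC and a chromosome 7 density ratio of 3.091. The overlap of the replicates, the annotation classes and the position of peaks in zinc finger genes kept their calls under every alternative run. Depth limits what a missing peak means, since reads per library are unknown. No paired analysis was possible because there was 1 group.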

Other observations

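The comparison of families and the tests of explanations were chosen after the patterns were seen, and those on the overall ratio of X peaks, on X peaks with −log10 q of at least 2 and on Y, with the random order of tied peaks, also after values were seen. Gene families outside the fixed lists were formed from the root of the gene symbol, which gave 229 families of at least 10 coding genes. Of these, 5 had more members with a replicated gene body peak than length-matched lists at an adjusted p below 0.05 and 0 had fewer. They were the secretoglobins (Scgb, 11 of 34 genes, 8.04 times), Ceacam (8 of 15, 6.59 times), the pregnancy-specific glycoproteins (Psg, 7 of 13, 6.16 times), Klra (7 of 11, 5.74 times) and Nlrp (9 of 16, 3.12 times), with adjusted p of 0.011 for the first 4 and 0.037 for Nlrp (two-sided permutation). The members of Ceacam, Psg and Klra each lie on a single chromosome. Scgb and Nlrp genes lie on 4 and 3 chromosomes, but Scgb2b26, Scgb2b27 and Scgb1b27 share the domain of 263.6 kb on chromosome 7. Members of these 5 families therefore cannot be taken as independent, and the shifts were not run for them.

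Replicate 1 had 1.956 times as many X chromosome peaks as replicate 2, and the autosomes lay between 0.990 and 1.075, which argues against a difference in the number of peaks called in all. The excess was spread along the chromosome, since the median ratio over 10 Mb windows of X was 1.969 and the highest median of an autosome was 1.071, which argues against a few regions. Among equal numbers of the strongest peaks of each replicate the ratio on X was 1.72 (exact 95% interval 1.528 to 1.938), against 0.940 to 1.072 on autosomes. With −log10 q of at least 2 it was 0.9398 (0.788 to 1.121), against 0.6495 to 0.773. Both intervals lay above the highest autosome ratio. The first set, however, reached down to a −log10 p of 4.329 in replicate 1, the median of its autosomal peaks. In the second, the interval of chromosome 15 (0.6659 to 0.8965) overlapped that of X. The tests therefore cannot decide whether weak peaks near the threshold are the whole cause. The X peaks were weaker, with a median −log10 p of 3.697 against 4.329 on autosomes in replicate 1 and 4.106 against 4.299 in replicate 2. Fewer of them were found in the other replicate (14.1% against 38.2% for replicate 1, 27.04% against 39.17% for replicate 2). Weak peaks may thus account for some or all of the excess. Another share of X and Y chromosomes in the sample than in its control could lift calls on X, but the ratio on Y was 1.053 (0.533 to 2.08), so few peaks that this cannot be told apart, and no biological explanation was tested because there was 1 group.

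The final exons of zinc finger genes were under peaks more often than the exons of other genes compared here. The other genes were those outside the symbol list, so zinc finger genes with other names stayed among them. How far these raise the counts of the other genes was not tested. Final exons of other coding genes matched on length and GC gave a mean of 11.4 under a peak (95% range 6 to 18) where the zinc finger genes had 121 of 414, a ratio of 10.62, which argues against exon length and GC content. Final exons of coding neighbours within 500 kb, nearest in exon length, gave 43.3 (35 to 52) where the zinc finger genes had 121 of 409, a ratio of 2.792, but these exons were shorter (median 1894.5 against 2243 bp) and had more GC (46.7% against 43.2%). A further test, set after those medians were seen, took neighbours within 5 percentage points of GC and 0.5 of log2 length. Of these, 25.2 (21 to 30) were under a peak where the zinc finger genes had 65 of 237. Location in peak-dense regions may thus account for part of the count. For the neighbours drawn, the tests argue against location as the whole cause. Their ranges cover only the draw among fixed neighbours (393 distinct genes in the last test), not the spread among clustered exons. Reads shared between related zinc finger genes were not tested, because the reads were not analysed here, and no biological explanation was tested.

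Chromosome 7 carries many genes of the clustered families, and 47.4% of its replicated peaks lay within 100 kb of a gene of the 11 lists defined by symbol, which took up 21.4% of its sequence. With that sequence left out on every chromosome, chromosome 7 still had 23.14 peaks per Mb, against 14.06 on chromosome 13, the densest of the other autosomes, and a median of 8.3. The listed clusters could therefore account for part of the density of chromosome 7 but not for its rank. Clusters outside these lists were not left out, such as the Ceacam and Scgb genes in domains of 301.9, 278.2 and 263.6 kb on this chromosome. Whether those account for the rank was not tested.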
